A study of Capra hircus with 12 samples.

How the data were processed

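RNA was profiled in 12 flasks of first-passage primary mammary epithelial cells from a lactating Saanen goat. Myoepithelial cells had been removed by selective trypsinization, per the labels' protocols. Groups were 3 control flasks and 3 flasks each at 3, 12 and 24 h after challenge, as given in the sample titles. The labels number the flasks without sharing a number between groups, so no samples were paired.

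Per the labels' protocols, polyadenylated RNA was selected with oligo-dT beads, fragmented and copied from random hexamers with a kit that does not mark the strand, and the 12 indexed libraries were pooled and sequenced as single reads. The deposited files hold whole-number read counts per RefSeq transcript accession, not normalized, and list only accessions with at least 1 read; this was checked on each of the 60 files. Every library had 5 files, from flow cells O3 and O4 (lanes 7 and 8 of each) and L5 (lane 8), with 411638 to 991541 counts per file. BWA 0.5.7, R 2.11.0 and edgeR 1.6.5 are named in the submitters' processing notes, without their roles. The reference sequences the reads were aligned to, the treatment of reads that match several transcripts and any mapping filter are not given in the sources used here. Counts per transcript cannot separate near-identical transcripts, nor antisense pairs, if reads were shared among them.

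Counts of the 5 runs were summed per library, and an accession missing from a file was taken as a count of 0. The runs of a library were checked against each other with the mean chi-square per transcript over accessions with at least 20 counts in the pair, which is about 1 for pure sampling noise; it was 0.97 to 1.03 within a flow cell and 0.99 to 1.18 between flow cells. All libraries were sequenced in every lane, so a lane or flow cell could not be confounded with a group. Replicates 3 and 11 had a smaller share of their reads on flow cell L5 (21.88% and 19.87%) than the other libraries (23.22% to 23.94%).

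Of the 19910 accessions 9135 were NM, 9423 XM, 112 NR and 1240 XR. Matched without their version against the RefSeq gene table of the goat genome, 0 were found. Whether the reference sequences were those of goat was therefore not settled here. No other annotation was used here, so gene names, coordinates and sums per gene were not analysed here, nor were 35 gene lists fixed before the data were examined. The rule for named genes, fixed at the same time, took the largest log2 fold changes upwards and downwards among those past the threshold with a mean of at least 5 CPM in a group. Since accessions had no names, it was applied to the first 2 upwards and 2 downwards of each comparison against control. Transcript length and GC content were not analysed here.

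Comparisons were fitted with edgeR 4.0.16 (R 4.3.3) on the summed counts: filterByExpr (minimum count 10, minimum total 15), TMM normalization, and the robust quasi-likelihood F-test (glmQLFit and glmQLFTest) on all 12 libraries in 4 groups with no covariate, giving 8 residual degrees of freedom. After filtering 12668 transcripts were tested. Transcripts with a Benjamini-Hochberg adjusted p under 0.05 are called changed. The biological coefficient of variation was 7.1%. Standard errors were obtained as the log2 fold change divided by the square root of F. CPM values were computed from the TMM-scaled library sizes. Of the 6 comparisons 5 were fixed before the data were examined, and 24 h against 3 h was added afterwards.

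The procedure was tested on counts simulated for all 12 libraries at their depths. Each transcript had its mean over all 12 libraries and its fitted spread, the same in every group, except for known changes at 24 h. For the comparison of 24 h with control, 70.1% of the 67 tested transcripts changed by 1.5-fold were recovered, as were 100% of the 65 tested at 2-fold and of the 65 tested at 3-fold; the filter had left out the rest of the 67 changed by 2-fold and the 66 changed by 3-fold. Of 12341 unchanged transcripts 14 were called. In a simulated comparison of 3 h with control without any change, 4 of 12538 were called. Counts were drawn from the fitted model itself, so these numbers do not give the error rate in the real data.

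Total counts ranged from 2527150 to 4265848 per library. A count of 3, the upper limit that a count of 0 allows, was 0.703 to 1.19 CPM; this limit covers counting error only, since reads amplified by PCR without molecular identifiers are not independent molecules.

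Alternatives fixed before the data were examined were RLE scaling, library size alone, no filter on low counts, at least 5 CPM in 3 libraries, each flow cell alone, the 2 compared groups alone, DESeq2 1.42.0, limma 3.58.1 (voom), edgeR's exact test, glmTreat against 1.5-fold, leaving out each replicate, and for overlaps an adjusted p under 0.01. Thinning all libraries to 2527150 counts, removing 5 accessions, and most alternatives of the overlaps were added after seeing the data. Figures were drawn with matplotlib 3.10.9.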

Results

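Transcript abundance was measured by RNA sequencing in primary mammary epithelial cells of a lactating Saanen goat after challenge with Mycoplasma agalactiae, a bacterium without a cell wall that causes contagious agalactia in goats and sheep. The design comprised 4 groups of 3 flasks: cells without bacteria, and cells collected 3, 12 and 24 h after addition of the PG2 strain at about 100 mycoplasmas per cell. Replicates were separate flasks of cells from 1 animal, so the p-values measure the spread between flasks and not between goats. The collection time of the control flasks is not given in the sources used here, so time in culture and time after challenge were not separated by any comparison against control.

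The 12 libraries held 39413880 counted reads in all. Control libraries held 3894256 ± 175980 counts (mean ± SD, n = 3), the 3 h libraries 2889336 ± 210104, the 12 h libraries 2812078 ± 331814 and the 24 h libraries 3542290 ± 823041. Single libraries ranged from 2527150 to 4265848 counts, and 15821 to 16905 of the 19910 listed transcript accessions had at least 1 read in a library. At these depths 3 counts corresponded to between 0.703 and 1.19 CPM, the count scaled to a fixed library total. The most abundant accession in every library was NM_001008663.1, with 4.11% to 5.17% of the counts. Features were RefSeq transcript accessions, which the files do not pair with gene names. Of the 19910, 0 matched the goat gene table used here, so transcripts are identified below by accession. Whether the reads were aligned to goat sequences or to those of another species was not settled.

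The libraries lay apart by time after challenge on the first principal component, while controls and 12 h libraries overlapped in their correlations. On the first principal component of log2 CPM, which held 30% of the variance, the 3 h libraries lay between -26.8 and -23.5, the controls between -6.4 and -0.2, the 12 h libraries between 7.3 and 10.1 and the 24 h libraries between 19.1 and 20.5. Spearman correlations across transcripts, which are not independent replicates, were 0.9832 to 0.9905 between replicates of a group. Between the 3 h and 24 h libraries their median was 0.9664, the lowest of any pair of groups, and between control and 12 h libraries it was 0.9828 with a range of 0.9775 to 0.9845, which overlapped the range between replicates. Control replicate 3 correlated with 12 h replicate 9 at 0.9842 and with the other controls at 0.9838 and 0.984. Control replicate 1 correlated with 12 h replicate 9 at 0.9845 and with control replicates 2 and 3 at 0.986 and 0.9838. The 24 h replicates 10 and 11 were the closest replicates by Spearman correlation, at 0.9905. Within a flow cell their mean chi-square per transcript was 1.13 on O3, 1.11 on O4 and 1.04 on L5, and in each single lane it was 1.04 to 1.07, where lanes of 1 library on the same flow cell gave 0.97 to 1.03. The other pairs of 24 h replicates gave 1.09 to 1.16 within a flow cell, and all 12 libraries were counted separately. Without 5 accessions described below and at 1 thinned total, replicates 11 and 12 were closer, at 1.12 against 1.16 for 10 and 11.

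**Figure D1:**
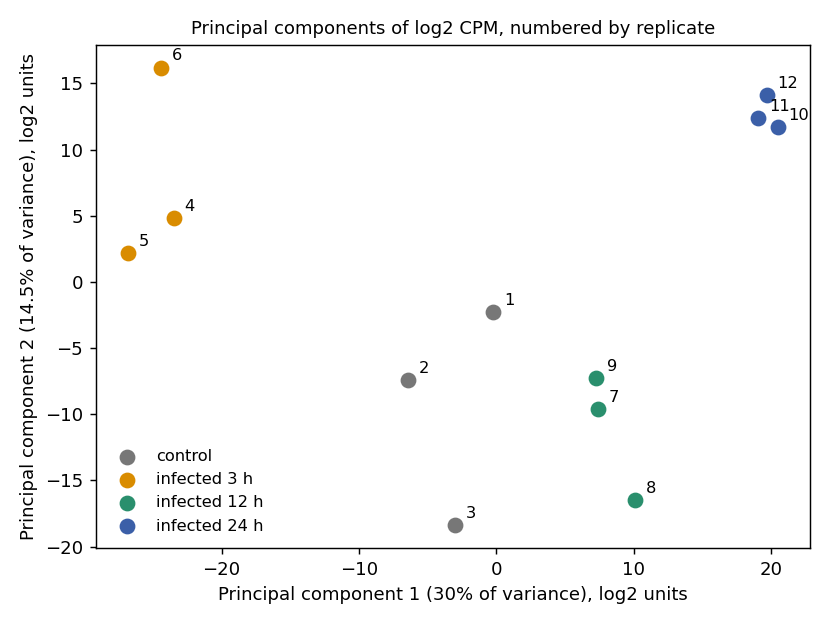
Scores of the 12 libraries on the first and second principal components of log2 CPM, which held 30% and 14.5% of the variance; each point is a library, coloured by group and numbered by replicate. The 3 h libraries lie at the left, between -26.8 and -23.5, and the 24 h libraries at the right, between 19.1 and 20.5.

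One control library stood apart in a few very abundant transcripts. In control replicate 3, the accessions XM_001252235.1, XM_001787664.1 and XM_001249389.2 were 5.58, 5.63 and 5.66 times as high as the mean of the other 2 controls, NM_174841.2 was 9.11 times and NM_181013.1 2.99 times as high. Together these 5 accessions, singled out after their values had been seen, took 5.03% of the counts in control replicate 3, 2.16% in 12 h replicate 7, 1.84% in 12 h replicate 8 and between 0.6% and 1.04% in each of the other 9 libraries. Without the 5 accessions the numbers of changed transcripts were 1158 at 3 h, 145 at 12 h and 1928 at 24 h against control, close to the 1167, 150 and 1927 with them.

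**Figure D2:**
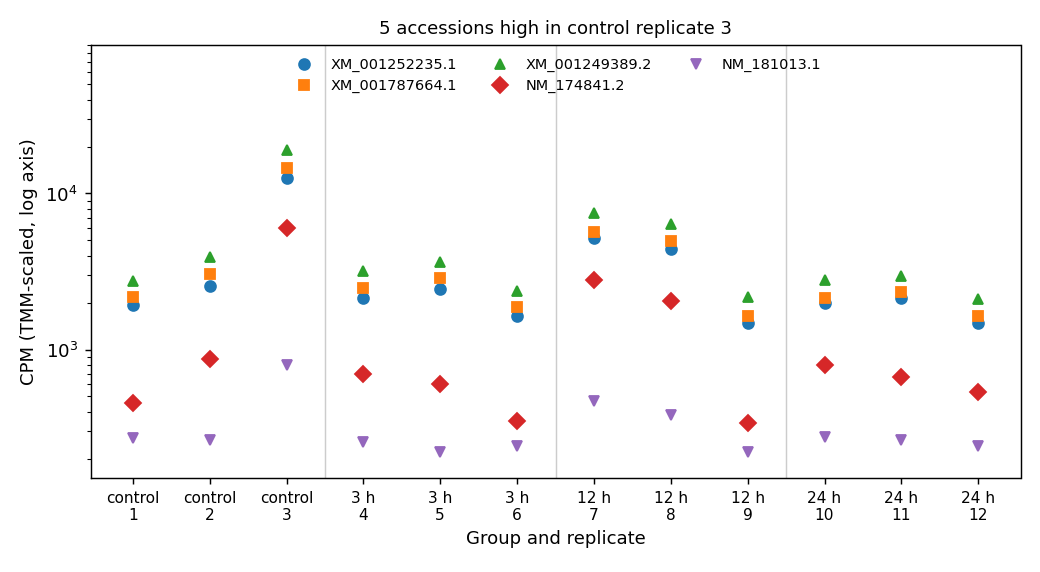
Abundance of 5 accessions in CPM (TMM-scaled, log axis) in each library, by group and replicate; each symbol is an accession. XM_001249389.2 reached 18905 CPM in control replicate 3, against 2741 and 3938 CPM in control replicates 1 and 2.

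The first comparison asked which transcripts differed from control cells 3 h after challenge. At that time 1167 of 12668 tested transcripts (9.21%) had changed, with 619 higher and 548 lower than in control. The changes were mostly modest: the median log2 fold change was 0.48 among the higher and -0.55 among the lower transcripts, while 50 were at least 2-fold higher and 55 at least 2-fold lower. XM_609882.4 rose from 21.6 ± 1.42 CPM in control to 81.5 ± 17.5 CPM at 3 h (mean ± SD, n = 3 each), a log2 fold change of 1.92 (SE 0.13, adjusted p = 4.44e-15 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). NM_174753.1 rose from 1.76 ± 0.757 to 6.33 ± 0.537 CPM (log2 fold change 1.83, SE 0.35, edgeR adjusted p = 0.000264). NM_001075620.1 fell from 11.2 ± 0.895 to 1.56 ± 1.09 CPM (log2 fold change -2.85, SE 0.35, edgeR adjusted p = 7.47e-08). At 3 h its libraries held 1.9, 0.333 and 2.44 CPM, the lowest from 1 count, so the size of this fall rests on few reads. It was -2.34 without 3 h replicate 5 and -3.35 without 3 h replicate 6. XM_864907.2 fell from 20.4 ± 1.94 to 5.77 ± 1.71 CPM (-1.82, SE 0.21, edgeR adjusted p = 2.78e-08). For each of these accessions all 3 libraries at 3 h lay on the same side of all 3 controls. They were chosen for large changes in these same libraries, so this is no separate support.

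Accessions of curated protein-coding transcripts (NM) were higher at 3 h in 350 cases and lower in 236 (361 and 219 with scaling by library size alone), and those of predicted protein-coding transcripts (XM) were higher in 234 and lower in 278 (249 and 247 with that scaling). Among the most abundant tertile of tested transcripts 352 were higher and 219 lower, whereas in the least abundant tertile 79 were higher and 115 lower. DESeq2 called 698 transcripts at 3 h, and a test against a minimum change of 1.5-fold called 26. That test asks for evidence that a change exceeds 1.5-fold and is not a cutoff on its estimated size. Among the called transcripts of the main fit, 216 higher and 248 lower ones had an estimated change of at least 1.5-fold. With the reads of a single flow cell 283 to 558 transcripts were called.

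**Figure D3:**
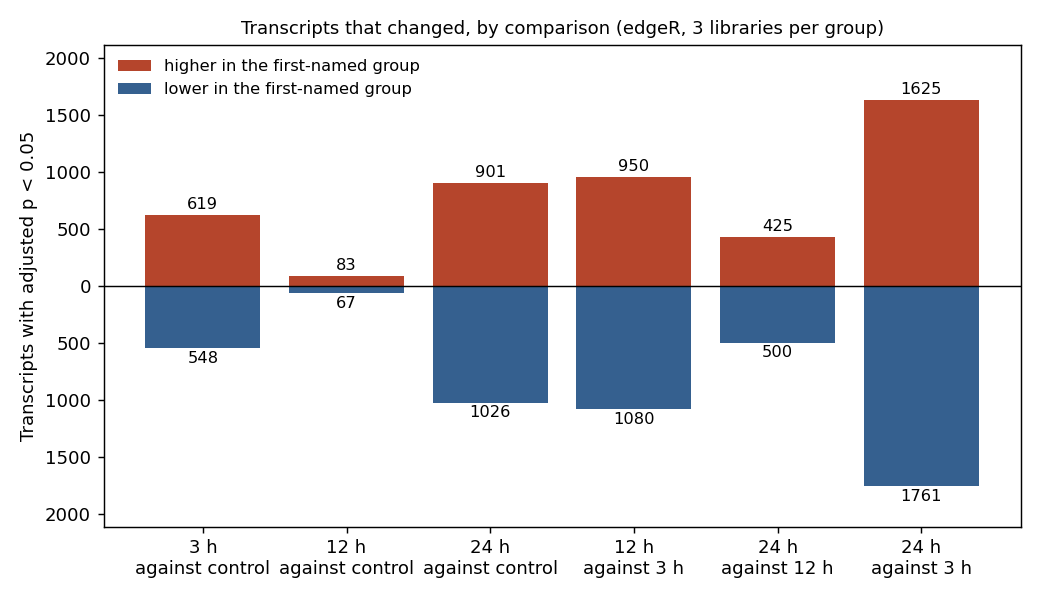
Numbers of transcripts with an adjusted p below 0.05 in each comparison (edgeR, 3 libraries per group); bars above 0 count transcripts higher in the first-named group and bars below 0 those lower. The 12 h comparison against control has the shortest bars, with 83 higher and 67 lower.

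At 12 h after challenge 150 transcripts (1.18% of those tested) differed from control, 83 higher and 67 lower, with 3 at least 2-fold higher and 3 at least 2-fold lower. NM_174838.2 rose from 4.39 ± 0.299 to 10.5 ± 1.17 CPM (n = 3 each; log2 fold change 1.26, SE 0.24, edgeR adjusted p = 0.00179). NM_001144090.1 rose from 9.62 ± 3 to 21.3 ± 1.84 CPM (1.13, SE 0.21, edgeR adjusted p = 0.000888) and had been higher still at 3 h, at 32.5 ± 8.1 CPM (log2 fold change 1.76). XM_588298.4 fell from 15.6 ± 1.93 to 4.49 ± 0.24 CPM (-1.80, SE 0.24, edgeR adjusted p = 8.78e-06), and XM_591370.3 fell from 18.2 ± 2.54 to 6.71 ± 2.08 CPM (-1.43, SE 0.22, edgeR adjusted p = 5.57e-05). In these 4 accessions too, every 12 h library lay on the same side of every control, again after choice from the same libraries. The call of NM_174838.2 ended on flow cells O3 (log2 fold change 1.09) and O4 (1.42), that of NM_001144090.1 on O3 (0.74) and that of XM_591370.3 on L5 (-1.30), and all 3 ended against a minimum change of 1.5-fold.

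The number at 12 h depended on single libraries more than at the other times. It was 310 without control replicate 3, 79 without control replicate 2, and 73, 65 and 83 without 12 h replicates 7, 8 and 9. When only the 6 control and 12 h libraries were fitted it was 73. DESeq2 called 93, single flow cells gave 34 to 68, and the test against a minimum change of 1.5-fold called 1. DESeq2 gave an adjusted p for only 7172 transcripts here. Single flow cells tested 9549 to 11107, where the main fit tested 12668. In the main fit 37 of the higher and 17 of the lower transcripts had an estimated change of at least 1.5-fold. Scaling by library size alone gave 157 higher and 36 lower transcripts (81.3% higher, against 55.3% with TMM scaling).

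At 24 h the largest number of transcripts differed from control, 1927 (15.21%), with 901 higher and 1026 lower. Their median log2 fold changes were 0.50 and -0.46, and 79 were at least 2-fold higher and 43 at least 2-fold lower. At 3 h the medians were 0.48 and -0.55, with 50 at least 2-fold higher and 55 at least 2-fold lower. The larger number at 24 h therefore does not by itself mean larger changes per transcript. NM_001035446.1 rose from 2.29 ± 0.632 to 8.94 ± 1.75 CPM (n = 3 each; log2 fold change 1.96, SE 0.31, edgeR adjusted p = 7.94e-06) and NM_001076259.1 from 1.92 ± 0.9 to 6.9 ± 0.539 CPM (1.83, SE 0.31, edgeR adjusted p = 3.53e-05). The accessions that fell furthest were the ones named at 12 h: XM_591370.3 was at 3.77 ± 0.554 CPM (log2 fold change -2.26, SE 0.23, edgeR adjusted p = 1.15e-09) and XM_588298.4 at 4.04 ± 0.932 CPM (-1.97, SE 0.23, edgeR adjusted p = 3.4e-08). All 3 libraries at 24 h lay on the same side of all 3 controls for each of them, again after choice from the same libraries.

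Curated protein-coding accessions were higher at 24 h in 593 cases and lower in 573, and predicted ones were higher in 249 and lower in 384. By library size alone 924 curated ones were higher and 390 lower, and 445 predicted ones were higher and 239 lower, so the balance of both classes depended on the scaling. In the most abundant tertile 412 transcripts were higher and 597 lower, and in the least abundant tertile 209 were higher and 132 lower. By library size alone 64.3% of the calls in the most abundant tertile were higher, against 40.8% with TMM, and 76.8% in the least abundant one, against 61.3%. The number of changed transcripts was 1234 without 24 h replicate 10, 1226 without 24 h replicate 11, 1141 with DESeq2, 31 against a minimum change of 1.5-fold and 531 to 1083 with single flow cells. Scaling by library size alone gave 1466 higher and 672 lower transcripts (68.6% higher, against 46.8% with TMM scaling).

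**Figure D4:**
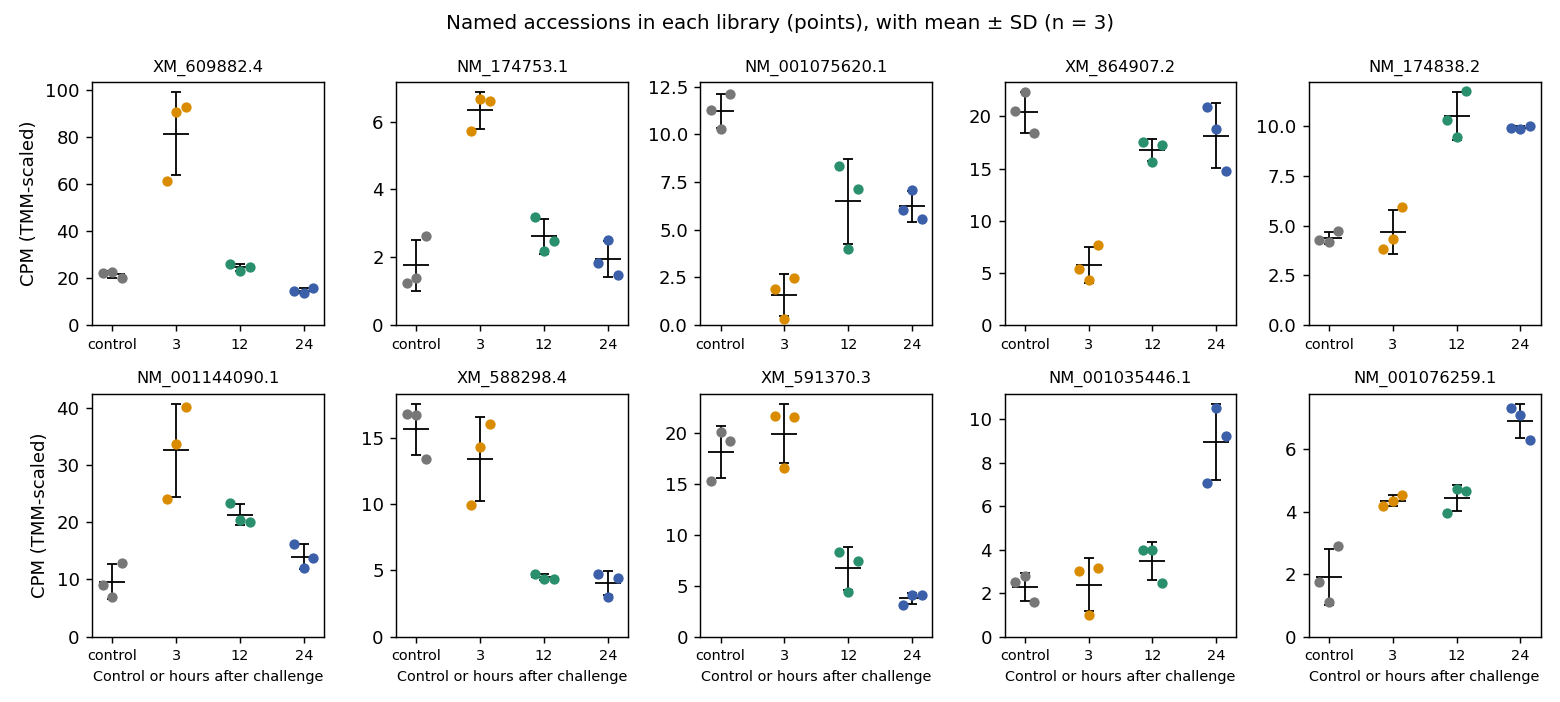
Abundance in CPM (TMM-scaled, vertical axes from 0) of the 10 named accessions in control cells and at 3, 12 and 24 h after challenge; points are libraries, and black marks give the mean ± SD (n = 3). XM_609882.4 reaches 81.5 CPM at 3 h and is at 24.5 CPM at 12 h, whereas XM_591370.3 is at 20 CPM at 3 h and at 3.77 CPM at 24 h.

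Between 3 h and 12 h, 2030 transcripts changed, 950 upwards and 1080 downwards, more than differed between 12 h and control. Of the 619 transcripts higher than control at 3 h, 483 fell between 3 h and 12 h, and of the 548 lower ones 368 rose; both comparisons use the 3 h libraries, whose chance deviations add to these numbers. XM_609882.4 fell to 24.5 ± 1.28 CPM at 12 h (log2 fold change between the times -1.74, SE 0.14, edgeR adjusted p = 3.35e-13), and XM_864907.2 rose again to 16.8 ± 1.03 CPM (1.54, SE 0.23, edgeR adjusted p = 3.45e-06). DESeq2 called 1268 transcripts for this step, the test against a minimum change of 1.5-fold called 59 and single flow cells gave 555 to 973. In the main fit 462 upward and 386 downward calls had an estimated change of at least 1.5-fold. Scaling by library size alone put 57.2% of the calls upwards, against 46.8% with TMM.

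Between 12 h and 24 h, 925 transcripts changed, 425 upwards and 500 downwards (506 and 407 with scaling by library size alone). Among the 901 transcripts higher than control at 24 h, 292 also rose over this step, and among the 1026 lower ones 349 also fell; both comparisons use the 24 h libraries, whose chance deviations add to these numbers, and the part they add was not measured. NM_001035446.1 rose from 3.48 ± 0.869 to 8.94 ± 1.75 CPM (n = 3 each; log2 fold change 1.38, SE 0.30, edgeR adjusted p = 0.00205), while XM_609882.4 fell further, to 14.7 ± 1.21 CPM (-0.75, SE 0.17, edgeR adjusted p = 0.00406). The number was 504 and 566 without 12 h replicates 8 and 9, and 497, 455 and 591 without 24 h replicates 10, 11 and 12. It was 1769 when only these 6 libraries were fitted, 602 with DESeq2, 1 against a minimum change of 1.5-fold, and 236 to 437 with single flow cells.

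A comparison of 24 h with 3 h, added after the calls against control had been seen, gave 3386 changed transcripts, 1625 higher and 1761 lower at 24 h, with 229 at least 2-fold higher and 143 at least 2-fold lower. XM_609882.4 differed by -2.49 on the log2 scale (SE 0.14, edgeR adjusted p = 2.83e-17) and XM_591370.3 by -2.39 (SE 0.24, edgeR adjusted p = 7.82e-11). The test against a minimum change of 1.5-fold called 249 transcripts, and single flow cells gave 1150 to 2038. In the main fit 726 higher and 691 lower transcripts had an estimated change of at least 1.5-fold. With scaling by library size alone 61.5% of the calls were higher at 24 h, against 48% with TMM.

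As sets, the transcripts changed at 3 h had medians near control levels later, with members on both sides. Those higher at 3 h had a median log2 fold change of -0.01 at 12 h and -0.01 at 24 h (quartiles -0.22 and 0.21 at 24 h), and those lower at 3 h one of -0.05 at both times. Of the 619 higher at 3 h, 87 were higher and 103 lower than control at 24 h, and of the 548 lower at 3 h, 69 were lower and 74 higher. Those higher at 24 h had medians of 0.04 at 3 h and 0.20 at 12 h, and those lower at 24 h had medians of 0.01 and -0.16. All these fold changes use the same controls, whose chance deviations push a set's medians at other times towards its own direction, and the size of that push was not measured. Of the transcripts changed at both 12 h and 24 h, 100 changed in the same direction (47 higher and 53 lower) and 1 in opposite directions, where independent lists would share 11.3 and 11.5. With scaling by library size alone 137 changed in the same direction at both times, 108 higher and 29 lower. At 3 h and 24 h, 156 changed in the same direction and 177 in opposite directions (88.4 and 89.1 for independent lists), and at 3 h and 12 h 17 and 19 did (7 and 6.9).

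Because these comparisons use the same controls, unchanged groups were simulated against them 20 times; on average 0.05 transcripts were then shared between 12 h and 24 h in the same direction, 0.05 between 3 h and 24 h and 0.1 between 3 h and 12 h. Almost nothing is called without a change, so these numbers do not measure what the shared controls add to the observed overlaps. Across transcripts, which are not independent replicates, the covariance of log2 fold changes was 0.0443 between 12 h and 24 h, against 0.0165 in the simulation. It was 0.0118 between 3 h and 24 h, against 0.0164, and 0.011 between 3 h and 12 h, against 0.0167. The simulation gave all groups the same fitted spread. The real controls deviated from each other with an SD of 0.194 to 0.229 in log2 units, against 0.136 to 0.155 at 24 h. The simulated covariances may therefore understate what the shared controls add. The corresponding correlations were 0.55, 0.12 and 0.14, against simulated values of 0.46, 0.46 and 0.44, and the same sign was seen in 68%, 52.9% and 53.1% of transcripts, against 65.4%, 65.4% and 64.8%. The simulated groups held no changes, so their fold changes spread less than the observed ones. The same covariance then gives a higher correlation and more equal signs. The simulated correlations and shares are therefore no baseline for the observed ones, and no conclusion is drawn from them. With 3 controls the shared libraries could not be divided into sets of at least 2, so part of any overlap may come from them. The overlap between 12 h and 24 h was 184 without control replicate 3, 48 without control replicate 2, 50, 45 and 53 without 12 h replicates 7, 8 and 9, and 64 and 63 without 24 h replicates 10 and 11. That between 3 h and 24 h was 100 and 95 without 24 h replicates 10 and 11. That between 3 h and 12 h was 42 without control replicate 3, 11 without 3 h replicate 4, and 9 and 10 without 12 h replicates 8 and 9.

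**Figure D5:**
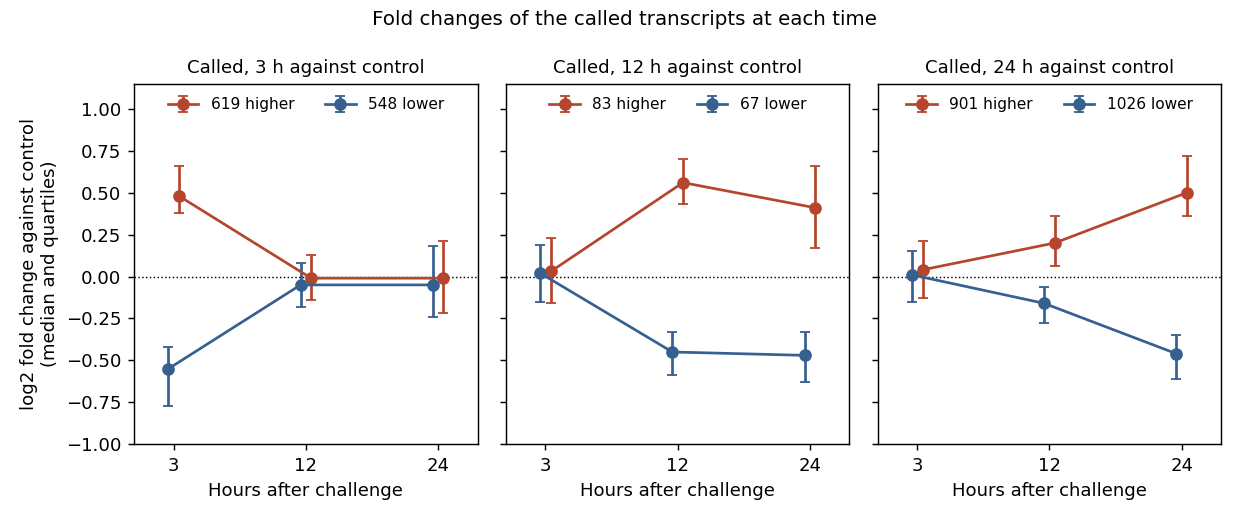
Median log2 fold change against control (points) with quartiles (bars) at 3, 12 and 24 h after challenge, for the transcripts called at 3 h (left), 12 h (middle) and 24 h (right); red marks transcripts called higher and blue those called lower. The 619 transcripts higher at 3 h have medians of 0.48, -0.01 and -0.01, and the 901 higher at 24 h have medians of 0.04, 0.20 and 0.50.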

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

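The comparison of 24 h with 3 h, the thinned counts and the tests of the abundance tertiles were chosen only after the calls against control had been seen, and the share of higher calls among abundant transcripts by library size alone was known before its test was set.

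The change against control differed between times in many transcripts. The tests are the comparisons between times given above, in which the controls cancel. The change differed in 2030 transcripts between 12 h and 3 h, in 925 between 24 h and 12 h and in 3386 between 24 h and 3 h (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Of the accessions named above, the level at 24 h differed from that at 3 h by a log2 fold change of -2.49 for XM_609882.4, -1.64 for NM_174753.1, 2.02 for NM_001075620.1, 1.67 for XM_864907.2, -1.24 for NM_001144090.1, -1.76 for XM_588298.4, -2.39 for XM_591370.3 and 1.91 for NM_001035446.1. NM_174838.2 differed by 1.16 between 12 h and 3 h. For NM_001076259.1 no difference between times passed the threshold. The named accessions were chosen for large changes in these same libraries, so chance deviations add to their differences.

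Regrouping the 6 libraries of each comparison gives 10 splits, too few for a share under 0.05, and in each comparison 1 of the 10, the real one, gave as many transcripts. The real split gave 1167 at 3 h, 150 at 12 h and 1927 at 24 h against control, and the highest of the other splits 73, 1 and 0. For 12 h against 3 h, 24 h against 12 h and 24 h against 3 h the real values were 2030, 925 and 3386, and the highest of the other splits 0 in each. Every other split mixes the 2 groups, so any difference between them widens the spread and leaves few calls. The splits therefore do not show how many calls would arise without a difference.

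Fewer transcripts differed from control at 12 h than at 3 h or 24 h. Lower depth is argued against: with all libraries thinned to 2527150 counts, 973, 128 and 1479 transcripts were called at 3, 12 and 24 h, and the 3 h count was 7.6 times the 12 h count. A single library that widened the spread is argued against as the whole cause, since the highest count at 12 h without 1 library was 310, without control replicate 3, below the 1167 at 3 h. Smaller changes at 12 h are in line with the covariance of fold changes between pairs of libraries that share none, which was at most 0.0292 at 12 h and at least 0.0333 at 3 h and 24 h. Whether this may reflect an early response that had ended and a later one that had begun, or an unstated collection time of the controls, stays open and was not tested.

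The share of higher calls rose with abundance at 3 h and fell with it at 24 h: in the most abundant tertile 61.6% of the calls were higher at 3 h and 40.8% at 24 h (64.3% with library size alone, so that its majority at 24 h depended on the scaling), and in the least abundant tertile 40.7% and 61.3%. For the difference between the tertiles the scaling is argued against as the whole cause: with RLE factors or library size alone it was at least 20.4 percentage points at 3 h, and at 24 h it was -12.5 with library size alone, reduced from -20.5 with TMM. At 3 h its size depended on control replicate 2, without which it was 13.6 points against 20.9, and it was 31.7 with DESeq2. Unequal depth is argued against for that difference as well, with 19.1 points at 3 h and -21.4 at 24 h after thinning, while transcript length and GC content, which could differ between abundance classes, and a link to the time after challenge stay open and untested.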

How the results depend on the processing

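The settings for 24 h against 3 h, those of the overlaps other than RLE scaling and an adjusted p under 0.01, the thinned counts and the removal of 5 accessions were chosen after seeing the data. In the 219 refits of named accessions that gave an adjusted p none changed direction; 212 stayed past the threshold and 7, all at 12 h, did not (3 of NM_174838.2, 2 of NM_001144090.1 and 2 of XM_591370.3). Another 21 gave none and say nothing about the calls: 14 on single flow cells, where the filter left the accession out, and 7 with DESeq2, which gave no adjusted p for NM_174753.1, NM_001035446.1, NM_001076259.1 or any of the 4 accessions at 12 h. All these refits use the libraries, or parts of them, from which the accessions were chosen, so they are no independent support. Of 120 refitted numbers of changed transcripts 77 stayed within 1.5 times the value reported and 43 did not; of 72 overlaps 39 did and 33 did not. RLE scaling, library size alone, voom, the exact test, both other filters, thinning and removal of 5 accessions kept all 6 numbers within 1.5 times. The cause of a shift was not tested. Single flow cells and left-out libraries do hold fewer reads or samples, and glmTreat asks for evidence that a change exceeds a minimum. The main fit used 1 spread per transcript for all groups. The SD of a library's log2 deviation from its other replicates was 0.194 to 0.229 in controls and 0.136 to 0.155 at 24 h. Numbers of changed transcripts may therefore not be directly comparable between comparisons. Whether this moved the numbers of the 2 groups alone was not tested.

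For 3 h, 12 h and 24 h against control, 12 h against 3 h, 24 h against 12 h and 24 h against 3 h, in this order, flow cell O3 alone gave 439, 34, 787, 790, 338 and 1601 changed transcripts, O4 558, 68, 1083, 973, 437 and 2038, and L5 283, 36, 531, 555, 236 and 1150. glmTreat against 1.5-fold gave 26, 1, 31, 59, 1 and 249. DESeq2 gave 698, 93, 1141, 1268 and 602 for the first 5. It gave an adjusted p for 11804, 7172, 10646, 11418 and 7944 transcripts there, where the main fit tested 12668. A transcript without an adjusted p was counted as not called in these numbers. The single flow cells O3, O4 and L5 tested 10481, 11107 and 9549 transcripts. The 2 groups alone gave 73 for 12 h against control and 1769 for 24 h against 12 h. Without 1 replicate the ranges were 65 to 310 for 12 h against control, 1226 to 2137 for 24 h against control and 455 to 635 for 24 h against 12 h; they were 790 to 1109 at 3 h, 1378 to 1647 for 12 h against 3 h and 2502 to 2999 for 24 h against 3 h.

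Same-direction overlaps of 3 h and 12 h, 3 h and 24 h, and 12 h and 24 h were 3, 49 and 23 on O3, 8, 63 and 46 on O4, 3, 26 and 22 on L5, 0, 0 and 1 with glmTreat, 7, 102 and 51 with 2 groups alone and 6, 58 and 40 at an adjusted p under 0.01. DESeq2 gave 73 for 3 h and 24 h and 59 for 12 h and 24 h. Without 1 replicate they were 9 to 42, 95 to 171 and 45 to 184.

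Library size alone moved the share of higher calls by over 10 percentage points in 4 comparisons: to 81.3% from 55.3% at 12 h, to 68.6% from 46.8% at 24 h, to 57.2% from 46.8% for 12 h against 3 h and to 61.5% from 48% for 24 h against 3 h. It turned the majority from lower to higher for 24 h against 12 h too, to 506 higher and 407 lower, and gave same-direction overlaps of 23 (22 higher, 1 lower), 178 (130 and 48) and 137 (108 and 29). Gene-list tests with all their alternatives, and sums per gene symbol, were not run, because no accession matched a symbol in the table used here. No paired analysis was possible because no replicate number is shared between groups. With all libraries at the lowest depth the numbers against control were 973, 128 and 1479.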

Other observations

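The correlations between comparisons without a common library and the 3 tests on the accessions of control replicate 3 were chosen after the data had been seen, the test of their ratios after its values were known.

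Curated protein-coding transcripts took most of the reads. NM accessions held 61.92% of the counts in control replicate 3 and 63.84% to 65% in the other 11 libraries, and NR and XR accessions together held 5.3% to 5.74% in all 12. At 24 h 17% of NM, 12.9% of XM and 14% of XR accessions had changed against control, and at 3 h 8.5%, 10.5% and 7.6% had. The abundance of the classes was not matched in these shares. The 10 most abundant accessions held 16.85 ± 0.81% of the counts in control, 15.43 ± 0.73% at 3 h, 15.12 ± 0.57% at 12 h and 14.15 ± 0.29% at 24 h (mean ± SD, n = 3).

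Comparisons that share no library are free of the effect of common controls. Across transcripts, which are not independent replicates, the fold changes of 12 h against control correlated with those of 24 h against 3 h with r = 0.32 (0.26 to 0.34 without any 1 library), and those of 24 h against control with those of 12 h against 3 h with r = 0.27 (0.22 to 0.29). For 3 h against control and 24 h against 12 h r was 0.01 (-0.04 to 0.07).

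Of the 5 accessions that were high in control replicate 3, the library itself rather than a sequencing run carried the excess: over the other 2 controls their sum was 5.55 to 5.71 times as high in each of the 5 runs, which argues against a faulty run. XM_001252235.1, XM_001787664.1 and XM_001249389.2 kept nearly fixed ratios over the 12 libraries, with an SD of at most 0.049 for the log2 ratio while their level varied over 3.18 log2 units, and NM_174841.2 did not, at 0.45; reads divided among near-identical sequences are a candidate explanation for the 3 moving as 1, though not for their rise. Without the 5 accessions, control replicate 3 still differed from the other controls by a mean chi-square per transcript of at least 2.63, against 9.8 and 8.46 with them and at most 2.35 for the other pairs of replicates, and it was closer to 12 h replicates 7, 8 and 9, at 2.24, 2.13 and 2.16. Nearness to 12 h libraries was not particular to control replicate 3. Control replicate 1 was also closer to 12 h replicates 7 and 9 (2.19 and 2.21) than to control replicates 2 and 3 (2.31 and 2.82). It was further from 12 h replicate 8 (3.29). A different composition of the whole of control replicate 3 stays open, and why these controls lay near 12 h libraries was not tested. Without control replicate 3 the number of transcripts changed at 12 h was 310 instead of 150. No biological explanation was tested, since the labels give no difference between the control flasks.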
